A study of Homo sapiens with 8 samples.

How the data were processed

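Biotin-labelled RNA from 8 tumours or metastases of human MDA-MB-435 cells grown in mice was hybridised to Illumina human bead arrays, 2 arrays in each of 4 groups (control or SPHK1 knockdown cells, mammary fat pad or lung). The authors read the arrays with GenomeStudio, per the submitters' processing notes, which give no version, and the report header states GSGX version 1.9.0 and normalization none. The deposited intensity is the mean over the beads of a probe on a linear scale, not normalized between arrays. Per the file headers each probe also has a bead standard error, a bead number and a detection p-value. The deposited log2 values are quantile-normalized between arrays, as read from their equal quantiles, and their background method is not given in the sources used here. The raw tables were equal at every shared value (largest difference 0). One of them holds 784 further features without a deposited log2 value, and 92 control probes lie in the probe profile. Background treatment within GenomeStudio and the genome build of the probe coordinates are not given in the sources used here.

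Intensities of 47323 probes were background-corrected and quantile-normalized with neqc of limma 3.58.1 (R 4.3.3, and data.table, version 1.17.8), with an offset of 16 and the background inferred from the detection p-values. Against the deposited log2 values, whose median was 4.57, these had a lowest r of 0.9999 across probes and a median absolute difference of 0.00881. Of 44053 probes with a symbol 35672 were matched to current gene names by Entrez identifier, which updated 8790. Probes with a detection p under 0.05 on at least 2 arrays were kept (21366), and the probe with the highest mean stood for each gene, which left 16589 genes, 1239 of them without a symbol. Between 16590 and 19273 probes were detected per array, and for arrays their number limits the precision.

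A linear model with a mean for each of the 4 groups was fitted with limma, with variances moderated by empirical Bayes (4 residual and 4.16 prior degrees of freedom). It gave 7 comparisons: knockdown against control and lung against fat pad, each averaged and within each stratum, and their interaction, which is the knockdown difference in lung minus that in the fat pad. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The labels do not say which samples share an animal, so the main fit did not pair arrays by replicate number. Correlations of replicate differences between groups ran from 0.0334 to 0.174, with 2 of 6 over 0.1, which leaves pairing undecided.

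For gene groups 37 lists fixed before the data were examined were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 37 lists of each comparison. They cover sphingolipid metabolism, NF-kappaB targets, actin and motility, epithelial-mesenchymal transition, matrix proteases, G1/S, G2/M, hypoxia, glycolysis, oxidative phosphorylation, cholesterol and fatty acid synthesis, the unfolded protein response, heat shock, immediate early genes, interferon response, MHC class I and II, melanocyte lineage, collagens, integrins, growth factors, p53 targets, apoptosis, metallothioneins, S100 genes, ribosomal proteins, housekeeping genes and 9 sets of host tissue markers. Those counts written as adjusted over the list alone use the members of 1 list as the family.

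Named genes followed a rule. SPHK1 and FSCN1 are named in each comparison. For each averaged comparison it adds the 8 rises and 8 falls with the largest log2 fold change past the threshold, with the same sign in both strata and detection on every array of the higher group, and for the other comparisons the 5 largest each way, or the 3 smallest p where none pass. From each list up to 4 members with the largest moderated statistic were eligible. Provisional names, open reading frame names and probes without a symbol were counted, not named. The text names a part of the eligible genes. A result for 1 eligible gene is not reported here.

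The alternatives, besides those for gene lists, were normexp with an offset of 50, no background correction, median scaling, cyclic loess, the deposited log2 values, no detection filter, detection on all 8 arrays, every detected probe, an intensity trend with robust variances, only the groups compared, a replicate block, a fold threshold, the other SPHK1 probe and each array left out in turn. Median scaling set equal the median over all probes of the profile except control probes, most of which were undetected on each array. Leaving out both arrays that stood apart was added after seeing the data. Splits of the 8 arrays into other groups of 4 were fitted with the second factor as an additive term, except the split that equals that factor. A slide block could not be run, since no slide is given. The workflow was tested on simulated data of 16589 genes with 100 changed genes per size. The averaged knockdown comparison recovered 80% of genes changed by 1 and 99% of those changed by 2 on the log2 scale, with 4.71% of calls false, the averaged site comparison 90% and 99% with 8.13%, and the fat pad comparison 35% and 98% with 2.21%. A shifted list was recovered with an adjusted p of 6.87e-30, and of 0.00688 with an estimated correlation, with 0 other lists called. The simulated genes varied independently, with no array standing apart and no batch, so these rates do not carry over to the real arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.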

Results

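RNA from tumours of the human line MDA-MB-435 was measured on 8 Illumina human bead arrays. The line is labelled breast cancer and is now known to share its origin with the melanoma line M14. Control cells carried a non-silencing hairpin, and knockdown cells carried a stably expressed hairpin against SPHK1, the sphingosine kinase that makes the signalling lipid sphingosine 1-phosphate. Both were injected into the mammary fat pad of mice, and tumours at that site were compared with the lung metastases that arose from them. The 4 groups, which are control fat pad, knockdown fat pad, control lung and knockdown lung, held 2 arrays each. The labels do not say whether the arrays of a group come from separate animals, so the p-values measure only the spread between these samples.

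Of 47323 probes, 16590 to 19273 per array were detected, which is 35.1% to 40.8%. The median deposited intensity was 94.8 to 100.5 on fat pad arrays and 87.0 to 92.5 on lung arrays. Each probe value rested on a median of 21 to 22 beads, with a median bead standard error of 4.07% to 4.34% of the intensity. After normalization the replicates of a group correlated across genes at r = 0.990 for control fat pad, 0.973 for knockdown fat pad, 0.974 for control lung and 0.988 for knockdown lung, where genes are not independent replicates. Control lung array 2 stood apart at 57.6 on the first principal component and knockdown fat pad array 2 at 47.6 on the third. The first component held 35.2% of the variance and was lowest, at -33.8, on knockdown fat pad array 1. That array had the highest mean deposited intensity (364), and control lung array 2 the lowest (212) and the fewest detected probes (16590). The other lung arrays had means of 271 to 288 and fat pad arrays 308 to 364, so array signal and site cannot be told apart. Tests covered 16589 genes, and the number of arrays limits the precision.

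The first comparison asks what SPHK1 knockdown changed in these tumours, averaged over both sites. SPHK1 was 3.31-fold lower in knockdown tumours, with a log2 fold change of -1.73 ± 0.262 (moderated standard error, 4 arrays a side, limma adjusted p = 0.0302). FSCN1, which encodes the actin-bundling protein fascin, was 3.62-fold lower (-1.86 ± 0.230, adjusted p = 0.0183). Mean normalized log2 values of SPHK1 were 6.79 in control and 5.07 in knockdown fat pad tumours, and 6.74 and 5.00 in lung metastases. For FSCN1 they were 10.03 and 8.09 in the fat pad and 9.95 and 8.18 in lung. With any 1 array left out the SPHK1 log2 fold change stayed between -1.96 and -1.49. The SPHK1 call ended without control fat pad array 1 or 2, knockdown fat pad array 1, or knockdown lung array 1 or 2. It also ended without the detection filter (adjusted p = 0.0733) and with a replicate block (adjusted p = 0.0512). The FSCN1 call ended without control fat pad array 1 or 2, knockdown fat pad array 2, or knockdown lung array 1 or 2 (adjusted p up to 0.109). The SPHK1 probe ILMN_2357134, detected on 7 of 8 arrays, reads chromosome 17 from 71895257 to 71895306, and the FSCN1 probe ILMN_1808707 reads chromosome 7 from 5612667 to 5612716, both on the plus strand of a build the files do not state. A further SPHK1 probe, ILMN_1774153, detected on 1 array, gave -0.21 (adjusted p = 0.612).

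**Figure D1:**
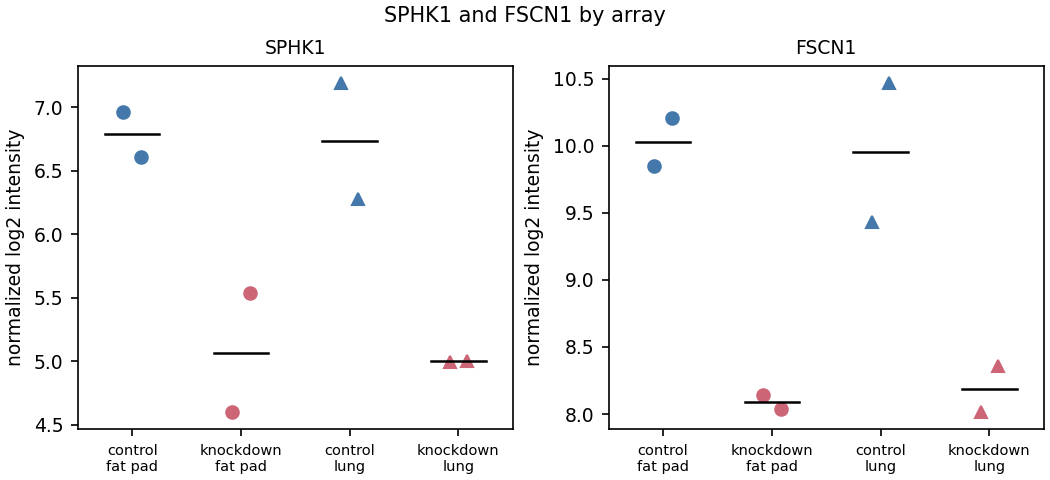
Normalized log2 intensity of SPHK1 and FSCN1 on each array, with control arrays in blue, knockdown arrays in red, and a bar at the mean of the 2 arrays of each group. FSCN1 means are 10.03 and 9.95 in the control groups and 8.09 and 8.18 in the knockdown groups.

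MT1E, a metallothionein that binds zinc and copper, was 14.4-fold lower (-3.85 ± 0.139, adjusted p = 3.88e-05). GPER1, a membrane receptor for oestrogen, was at least 8.05-fold lower (-3.22 ± 0.183, adjusted p = 0.000736), and its other probe gave -2.97. PMP2, a fatty acid-binding myelin protein, was 23.0-fold lower (-4.53 ± 0.659, detected on 7 of 8 arrays), and COL5A2, a fibrillar collagen chain, was 14.8-fold lower (-3.88 ± 0.377, 6 arrays). MAOA, which oxidises monoamines, fell at least 7.47-fold (-3.13 ± 0.376, 5 arrays), and RGS2, a brake on G protein signalling, fell 6.08-fold (-2.60 ± 0.210, 6 arrays). CFI, a complement protease, changed by -2.48 ± 0.292, and FGFRL1, a growth factor receptor without a kinase, by -2.63 ± 0.441, with -1.09 at its other probe. A fold is written as at least N-fold where a gene was undetected on every array of a group. It is then taken against the lowest normalized log2 value among detected probes of each array, 4.75 to 4.96. MT1E and GPER1 kept their calls without any 1 array. The other 6 calls each ended without control fat pad array 1 or 2 and, for all but RGS2, without knockdown lung array 1, with further losses without knockdown lung array 2 (PMP2, MAOA, FGFRL1), knockdown fat pad arrays 1 and 2 (PMP2, FGFRL1) and control lung array 2 (FGFRL1), at adjusted p up to 0.179.

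The largest rises were smaller than the largest falls. CDKN1A, the cyclin-dependent kinase inhibitor p21, rose by 1.19 ± 0.157 (adjusted p = 0.0202), and IRX3, a homeobox transcription factor, by 1.27 ± 0.153 (adjusted p = 0.0174). SHROOM3, which couples actin to cell shape, rose by 1.26 ± 0.159, SCG5, a neuroendocrine chaperone, by 1.28 ± 0.171, and INAVA, an adaptor of innate immune signalling, by 1.33 ± 0.187. GPR143, a receptor of the melanosome, rose by 1.25 ± 0.219 (adjusted p = 0.0479). The non-coding RNAs LINC00326 (1.55 ± 0.146, adjusted p = 0.00711) and PAX8-AS1 (1.22 ± 0.175, at least 2.12-fold) rose too. All 8 calls ended without control fat pad array 1 or 2 or knockdown lung array 1, at adjusted p up to 0.212. Without knockdown lung array 2 the calls of INAVA, SCG5, IRX3, SHROOM3, GPR143 and CDKN1A ended, without knockdown fat pad array 1 those of INAVA and PAX8-AS1, without knockdown fat pad array 2 those of SCG5, GPR143 and PAX8-AS1, and without control lung array 2 that of GPR143.

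Cell cycle genes were higher in knockdown tumours. All 30 measured G2/M genes read higher, with 4 past the test over all genes and 29 when adjusted over the list alone (median log2 fold change 0.58, camera adjusted p = 5.08e-23, adjusted p = 0.215 with an estimated correlation). The 4 were the mitotic cyclin CCNB2 (0.86 ± 0.116), the ubiquitin-conjugating enzyme UBE2C (0.87), the mitotic kinase AURKA (0.91) and the proliferation marker MKI67 (0.78). Among 29 G1/S genes 3 rose, 17 adjusted over the list alone, with a median of 0.42 (adjusted p = 1.5e-10, adjusted p = 0.215 with an estimated correlation). They were GINS2 (0.80) of the replicative helicase, cyclin CCNE2 (0.92) and the chromatin assembly factor CHAF1A (0.79). All 7 gene calls ended without control fat pad array 1 or 2, knockdown fat pad array 1, or knockdown lung array 1 or 2, all but CCNE2 without knockdown fat pad array 2, and all but CCNB2 and UBE2C without control lung array 2 (adjusted p up to 0.223). In the same tumours 1 of 19 p53 targets, CDKN1A, rose (median -0.02, mean 0.00, adjusted p = 0.915).

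Genes of lipid synthesis and respiration read higher as lists. The 23 cholesterol synthesis genes had a median of 0.28 (adjusted p = 6.73e-05, adjusted p = 0.351 with an estimated correlation), with MVD, a decarboxylase of the mevalonate pathway, at 0.76 (adjusted p = 0.0667). Of 33 oxidative phosphorylation genes 30 read higher, 0 passed over all genes and 2 adjusted over the list alone, among them NDUFA6 of complex I at 0.84 (list median 0.21, adjusted p = 1.51e-05, adjusted p = 0.585 with an estimated correlation). The 13 fatty acid synthesis genes had a median of 0.23, with 0 past the test over all genes and 2 adjusted over the list alone, and ELOVL6, a fatty acid elongase, at 0.48 (adjusted p = 0.0251, adjusted p = 0.282 with an estimated correlation). That list call ended without control lung array 1 or knockdown lung array 1 (adjusted p up to 0.0603). The 25 unfolded protein response genes had a median of 0.20, with 0 past the test, and 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.0277, adjusted p = 0.282 with an estimated correlation). Its members ASNS, which makes asparagine, and TRIB3, a stress pseudokinase, read 0.65 and 0.79. That call ended without knockdown fat pad array 1, control lung array 2 or knockdown lung array 1 (adjusted p up to 0.0904).

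Interferon-induced genes were lower in knockdown tumours. Of 36 measured, 34 read lower, 10 fell over all genes, and 31 fell and 1 rose adjusted over the list alone (median -0.68, adjusted p = 2.88e-23, adjusted p = 0.282 with an estimated correlation). The antiviral GTPase MX1 fell by 1.37 ± 0.177 on the log2 scale, the RNA sensor OAS2 by 1.21 and SAMD9 by 1.16 ± 0.134. The other OAS2 probes gave log2 fold changes of -0.74, -0.13 and 0.30. The RNA-binding IFIT1 was 2.14-fold lower (adjusted p = 0.0172), with a log2 fold change of 0.25 at its other probe. These 4 calls ended without control fat pad array 1 or 2 or knockdown lung array 1 or 2, and OAS2 also without knockdown fat pad array 1 or 2 (adjusted p up to 0.122). The 18 genes of MHC class I presentation had a median of -0.33, with 0 past the test over all genes and 3 adjusted over the list alone, HLA-B at -0.79 (adjusted p = 0.000343, adjusted p = 0.282 with an estimated correlation). For 9 genes of MHC class II presentation the median was -1.66, with 0 past the test and 6 adjusted over the list alone, and CD74, the invariant chain, at -3.40 ± 0.717 (adjusted p = 6.63e-05 for the list, adjusted p = 0.47 with an estimated correlation). This list stood at 2.50 above its genes' mean on control lung array 2. Its median was -0.71 without that array and -2.61 without control lung array 1.

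Matrix and fibroblast genes were lower in knockdown tumours. Of 22 collagen and matrix genes 3 fell, and 5 fell and 1 rose adjusted over the list alone (median -0.26, adjusted p = 0.000361, adjusted p = 0.367 with an estimated correlation). Besides COL5A2 they were COL6A2 (-1.35 ± 0.177, at least 2.10-fold) and COL1A2 (-1.05 ± 0.136, at least 1.78-fold). All 9 fibroblast markers read lower, 1 past the test, COL1A2, and 3 adjusted over the list alone, and FAP, a fibroblast surface protease, read -0.80 (list median -0.50, adjusted p = 1.68e-05, adjusted p = 0.282 with an estimated correlation). Other lists hold 3 of the 9, and 4 of the 9 were detected on every fat pad array. SNAI2, a repressor of epithelial genes (-1.27 ± 0.136), CTSK, a collagen-degrading protease (-1.70 ± 0.188, at least 3.15-fold), and ITGA10, a collagen-binding integrin (-1.64 ± 0.219), fell as well. Without control lung array 2 and knockdown fat pad array 2 together, a setting chosen after seeing the data, the collagen list had an adjusted p of 0.0769. Except for COL5A2, these gene calls ended without control fat pad array 2 or knockdown lung array 1 or 2, all but CTSK without control fat pad array 1, and COL6A2, COL1A2 and ITGA10 without knockdown fat pad array 2 (adjusted p up to 0.120).

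All 6 metallothioneins read lower, with MT1E past the test and 4 adjusted over the list alone (median -0.50, adjusted p = 5e-05, adjusted p = 0.282 with an estimated correlation). MT1X read -0.73. Of 11 S100 calcium-binding genes S100A3 fell (-1.21 ± 0.187), and 2 fell and 1 rose adjusted over the list alone (median -0.21, adjusted p = 0.0143, adjusted p = 0.282 with an estimated correlation). The S100 list call ended without knockdown fat pad array 2 (adjusted p = 0.064), and the S100A3 call without any 1 array except knockdown fat pad array 2 and control lung array 1 (adjusted p up to 0.157). The 19 growth factor and angiogenesis genes had 0 past the test and 4 lower adjusted over the list alone (median -0.18, adjusted p = 0.0315, adjusted p = 0.531 with an estimated correlation). IGFBP5, a carrier of insulin-like growth factors, read -2.34 ± 0.428 (adjusted p = 0.0536), and PTN, the growth factor pleiotrophin, -1.47. That call ended without knockdown fat pad array 2 or control lung array 2 (adjusted p up to 0.327).

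The lists nearest to the study's question were not called in this comparison. Of 27 sphingolipid genes only SPHK1 passed over all genes (median -0.05, adjusted p = 0.598), and of 37 actin and cell protrusion genes only FSCN1 (-0.06, adjusted p = 0.321). The 22 NF-kappaB targets had a median of -0.09 (adjusted p = 0.710) and the 19 genes of epithelial-mesenchymal transition -0.09 (adjusted p = 0.290, SNAI2 past the test). Matrix proteases had a median of 0.02 and a mean of -0.11 (adjusted p = 0.505), and integrins 0.02 and -0.06 (adjusted p = 0.651). The 24 melanocyte genes had a median of -0.19 (adjusted p = 0.0850), called under 2 of 6 background and normalization settings. Medians were -0.12 for hypoxia (adjusted p = 0.321), -0.03 for glycolysis (0.853), 0.20 for heat shock (0.0772, called under 3 of 6 such settings), -0.09 for immediate early genes (0.171) and -0.04 for apoptosis regulators (0.638). Ribosomal proteins had a median of 0.03 and a mean of -0.01 (adjusted p = 0.853), and housekeeping genes a median of 0.06 (0.546).

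Host tissue lists other than fibroblasts were not called between knockdown and control. The 5 endothelial markers had a median of 0.02 (adjusted p = 0.651), with ROBO4, an endothelial guidance receptor, higher (1.02 ± 0.141). That gene call ended without any 1 array except knockdown fat pad array 1 and control lung array 1 (adjusted p up to 0.126). Macrophage markers had a median of 0.01 and a mean of -0.03 (adjusted p = 0.748). Lung epithelium had -0.01 (adjusted p = 0.976), mammary epithelium 0.14 (0.477), adipocytes -0.05 (0.651), lymphocytes 0.04 (0.508), muscle -0.23 (0.0770) and erythroid cells 0.08 (0.564).

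In all, limma called 51 genes higher and 94 lower in knockdown tumours, 16 and 77 of them by 2-fold or more, with 2613 genes at an unadjusted p under 0.05 where chance gives 829. The balance of higher and lower calls depended on the setting. It was 63 and 133 with cyclic loess, 226 and 261 with an intensity trend and robust variances, and 102 and 90 with detection on all 8 arrays. Without 1 array the calls numbered 4 (control fat pad 1), 3 (control fat pad 2), 93 (knockdown fat pad 1), 61 (knockdown fat pad 2), 707 (control lung 1), 90 (control lung 2), 4 (knockdown lung 1) and 16 (knockdown lung 2). Without both arrays that stood apart 110 genes were called. Camera called 6 lists up and 8 down of 37, of which 0 held with an estimated correlation (5 at an unadjusted p under 0.05), and fry called 7.

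At each site alone few genes passed. In the fat pad limma called 0 genes higher and 10 lower (1444 at an unadjusted p under 0.05). They include MT1E (-3.97 ± 0.197, adjusted p = 0.000495), RGS2 (-2.98, adjusted p = 0.0196), GPER1 (-2.95 ± 0.258), IFIT1 (-2.06 ± 0.185, adjusted p = 0.0133), MX1 (-2.12 ± 0.250, adjusted p = 0.0480) and OAS2 (-1.93). In lung metastases 0 rose and MT1E (-3.73 ± 0.197, adjusted p = 0.000811) and GPER1 (-3.48 ± 0.258, at least 8.37-fold, adjusted p = 0.00614) fell (2455 at an unadjusted p under 0.05). SPHK1 and FSCN1 had adjusted p of 0.201 and 0.107 in the fat pad and 0.145 and 0.130 in lung. MT1E kept both calls without any 1 array. In the fat pad RGS2, GPER1 and IFIT1 were lost without control fat pad array 1 or 2 or knockdown fat pad array 2 (adjusted p up to 0.245), and MX1 and OAS2 also without knockdown fat pad array 1 or knockdown lung array 1 or 2 (up to 0.508). GPER1 in lung was lost without control lung array 2 or knockdown lung array 1 or 2 (up to 0.129). Left out singly, arrays moved these counts between 1 and 47 in the fat pad and between 1 and 556 in lung.

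The knockdown differences at the 2 sites share no arrays and correlated across genes at r = 0.278 (Spearman 0.186), where genes are not independent replicates. Of 518 genes at an unadjusted p under 0.05 at both sites 489 went the same way, 219 up and 270 down, where independence gives 50.6 and 55.7. G2/M genes had medians of 0.59 in the fat pad and 0.62 in lung, with 30 of 30 higher at each site (adjusted p = 1.48e-20 and 9.31e-15). With an estimated correlation these were adjusted p = 0.23 and 0.355.

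The second comparison asks how lung metastases differ from tumours at the injection site, averaged over both lines. EFNB2, an ephrin ligand of arterial endothelium, read 26.9-fold higher in lung (4.75 ± 0.310, adjusted p = 0.000637). The matrix protein gene SPARCL1 read 19.7-fold higher (4.30 ± 0.252), the endothelial phosphatase gene PTPRB 19.3-fold (4.27 ± 0.253, 7 of 8 arrays) and HBA2, an alpha globin, 14.9-fold (3.90 ± 0.193, adjusted p = 0.000166). CYP4B1, a cytochrome P450 of lung tissue, was at least 9.98-fold higher (3.72 ± 0.122, detected on 4 arrays, adjusted p = 1.73e-05), and the transcription factor DACH1 at least 14.7-fold (3.96 ± 0.304, 5 arrays). PDGFA, a growth factor, read 4.15 ± 0.388 and PRDX1, a peroxidase, 4.11 ± 0.480. Probes of the same gene disagreed for HBA2 (-0.04 at the other probe), PRDX1 (-0.76) and PDGFA (0.76). Among the falls were STX8, a vesicle fusion protein (-1.98 ± 0.141, adjusted p = 0.000987), TAF15, an RNA-binding protein (-1.56 ± 0.143), and PIAS4, a SUMO ligase (-1.51 ± 0.133). These named calls held without any 1 array, except PRDX1, which was lost without control fat pad array 1 or 2 or knockdown lung array 2 (adjusted p up to 0.0606).

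Further falls were those of ENO2, a glycolytic enolase (-1.53 ± 0.169), APP, the amyloid precursor (-1.60 ± 0.223, with -1.27 and -1.89 at its other probes), SLC5A3, an inositol transporter (-1.59 ± 0.289), RNF150, a RING finger protein (-1.39 ± 0.196), and the non-coding RNA OLMALINC (-1.34 ± 0.234). They were lost without control fat pad array 1 or 2, all but RNF150 without knockdown lung array 2, APP, SLC5A3 and OLMALINC without knockdown lung array 1, SLC5A3 and OLMALINC without knockdown fat pad array 2, OLMALINC without knockdown fat pad array 1 and SLC5A3 without control lung array 2 (adjusted p up to 0.144). SPHK1 read -0.06 ± 0.262 (adjusted p = 0.927) and FSCN1 0.01 (adjusted p = 0.990) between sites.

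**Figure D2:**
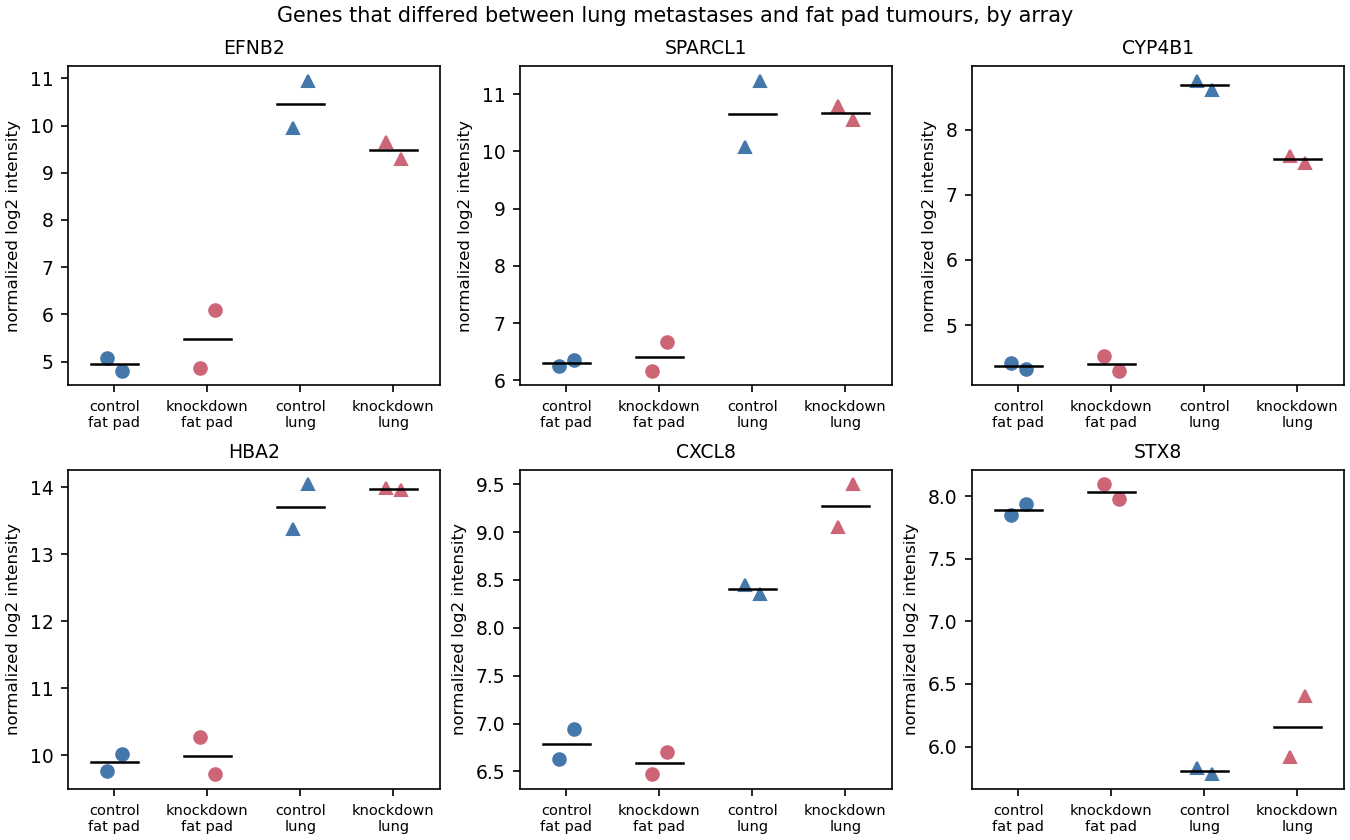
Normalized log2 intensity per array of 5 genes higher in lung metastases (EFNB2, SPARCL1, CYP4B1, HBA2, CXCL8) and 1 gene lower (STX8), with control arrays in blue, knockdown arrays in red, circles for fat pad and triangles for lung, and a bar at each group mean. The averaged log2 fold changes run from 4.75 for EFNB2 to -1.98 for STX8.

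Interferon-induced genes were higher in lung metastases. Of 36 interferon genes 35 read higher, 19 rose over all genes and 31 adjusted over the list alone (median 0.86, adjusted p = 3e-27, adjusted p = 0.35 with an estimated correlation). IFIT2 rose by 1.72 ± 0.141, IFIT1 by 1.58 ± 0.131 with 0.71 at its other probe, IFIT3 by 1.67 and the RNA sensor IFIH1 by 1.22, and only the IFIH1 call ended without an array, control fat pad array 1 (adjusted p up to 0.051). Of 22 NF-kappaB targets 4 rose, also 4 adjusted over the list alone (median 0.14, but -0.26 when arrays were scaled to equal medians, adjusted p = 0.0249, adjusted p = 0.35 with an estimated correlation). CXCL8, the chemokine interleukin 8, which mice lack, rose by 2.15 ± 0.152 (adjusted p = 0.000987, 1.77 at its other probe), and kept its call without any 1 array. SOD2, a mitochondrial superoxide dismutase, rose by 1.70 ± 0.216 with 0.55 at its other probe, the NF-kappaB inhibitor NFKBIA by 1.59 and IRF1 by 0.63. Without control fat pad array 1 or 2 or knockdown lung array 2 the SOD2, NFKBIA and IRF1 calls ended, NFKBIA and IRF1 without knockdown lung array 1, and IRF1 without knockdown fat pad array 1 or 2 or control lung array 2 (adjusted p up to 0.798 over all settings, the highest under median scaling). The NF-kappaB list call ended without control lung array 1 (adjusted p = 0.066). The 18 MHC class I genes had a median of 0.30, which was -0.18 under median scaling, with CALR lower, and 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.0089, adjusted p = 0.522 with an estimated correlation, 0.0717 without control lung array 2).

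Hypoxia and glycolysis genes were lower in lung metastases. Of 27 hypoxia genes 7 fell, and 15 fell and 1 rose adjusted over the list alone (median -0.48, adjusted p = 3.87e-08, adjusted p = 0.35 with an estimated correlation). BNIP3, a mitophagy receptor, fell by 0.84 ± 0.121 on the log2 scale and the glucose transporter SLC2A3 by 0.93, and DDIT4, an mTOR inhibitor, fell too (adjusted p = 0.0186). All 19 glycolysis genes read lower, 3 past the test and 13 adjusted over the list alone (median -0.45, adjusted p = 9.76e-09, adjusted p = 0.223 with an estimated correlation), among them TPI1, a triose isomerase (-0.67), and ENO2. The lists share 4 genes. Metallothioneins had a median of -0.45, with MT1X past the test, also 1 adjusted over the list alone (-1.19 ± 0.211, list adjusted p = 0.00274, adjusted p = 0.517 with an estimated correlation). The BNIP3, DDIT4, SLC2A3, TPI1 and MT1X calls ended without control fat pad array 1 or 2 or knockdown lung array 1 or 2, SLC2A3 and TPI1 without knockdown fat pad array 1, SLC2A3 and MT1X without knockdown fat pad array 2, and TPI1 without control lung array 2 (adjusted p up to 0.179). The 36 ribosomal proteins had a median of -0.19, with 0 past the test over all genes or over the list alone (adjusted p = 0.0089, adjusted p = 0.522 with an estimated correlation, 0.0773 without knockdown fat pad array 1). The 30 G2/M genes had 0 past either and a median of 0.15, which was -0.36 under median scaling (adjusted p = 0.0155, adjusted p = 0.522 with an estimated correlation). That call ended without control fat pad array 1, knockdown fat pad array 2 or knockdown lung array 1 (up to 0.115).

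Markers of host tissue read higher in lung for some lists. Of 5 erythroid genes HBA2 and HBD (0.85, at least 1.41-fold) rose, 3 adjusted over the list alone (median 0.81, adjusted p = 0.000624, adjusted p = 0.35 with an estimated correlation). AQP5, a water channel of alveolar epithelium, rose by 3.09 ± 0.322 (at least 6-fold) as 1 of 5 lung epithelium markers (median 0.22, adjusted p = 0.165). Of 9 fibroblast markers FBLN1 (1.43 ± 0.216, at least 2.19-fold, 0.14 at its other probe) and the complement gene C1S (1.36) rose (median 0.29, adjusted p = 0.0890). The endothelial tight junction gene CLDN5 rose by 0.99 (at least 1.46-fold, list median -0.02, mean 0.09, adjusted p = 0.771) and the lymphocyte receptor IL7R by 1.05, with 0.35 at its other probe (list median 0.23, adjusted p = 0.208). Of these, AQP5 was lost without control fat pad array 1 (adjusted p up to 0.051), C1S without that array, knockdown fat pad array 1 or knockdown lung array 1 or 2, and HBD, FBLN1, CLDN5 and IL7R without control fat pad array 1 or 2 or knockdown lung array 1 or 2 (up to 0.163). HBD and CLDN5 were lost without knockdown fat pad array 1, HBD, CLDN5 and IL7R without knockdown fat pad array 2, and HBD and IL7R without control lung array 2. Medians were 0.10 for mammary epithelium (adjusted p = 0.469), 0.07 for adipocytes (0.914), 0.21 for macrophages (0.245) and 0.53 for muscle (0.117). Of 101 other detected probes of 77 genes that rose in lung 17 followed the rise with the same sign and at least 50% of its size. That is a share of 16.8% (95% Clopper-Pearson interval 10.1 to 25.6). Some of these probes lay near the floor, such as those of FBLN1 and APOL3 with means of 4.63 and 4.67, where a rise can be missed. Their number in each set was not counted. For 44 genes changed by knockdown the share was 40 of 60 probes, or 66.7% (53.3 to 78.3, Fisher's exact p = 2.35e-10, two-sided). It was made up of 95.5% of 22 probes of genes that rose and 50% of 38 probes of genes that fell. For 37 genes that fell in lung it was 21 of 46 probes, or 45.7% (30.9 to 61.0, Fisher's exact p = 0.0469 against genes changed by knockdown). These intervals and tests count probes as independent though some share a gene, so intervals may be too narrow and p-values too small.

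**Figure D3:**
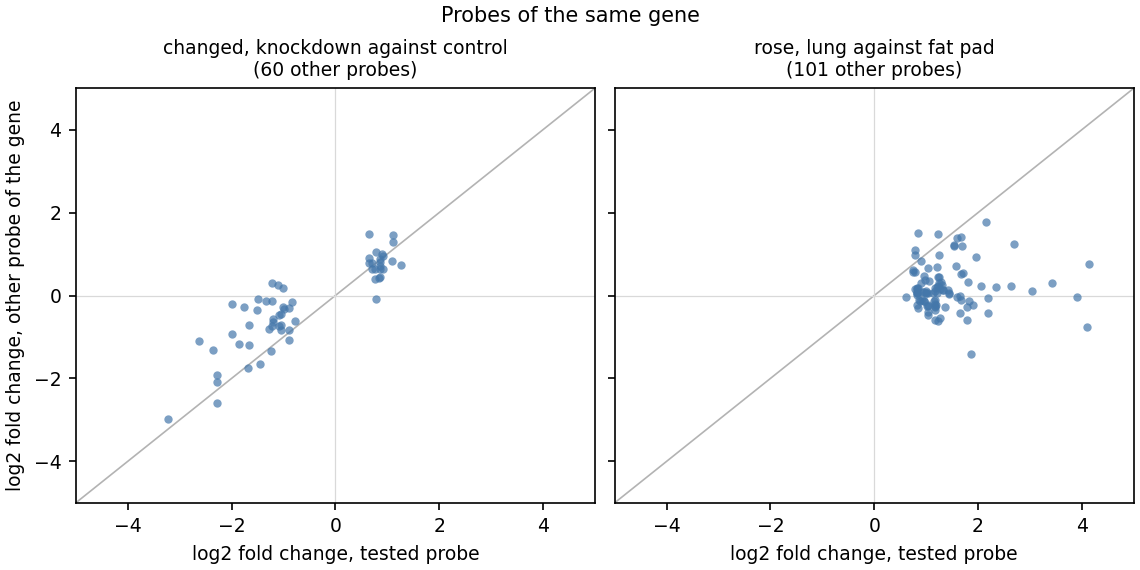
Log2 fold change of the tested probe of each gene against that of its other detected probes, at left for 60 probes of genes changed by knockdown and at right for 101 probes of genes higher in lung, with the diagonal marking equal values. On the left 66.7% of the other probes follow the tested one, on the right 16.8%.

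The remaining lists were not called between sites averaged over cells with the settings used. Single genes past the test in them were THBS1, the matrix protein thrombospondin (1.40 ± 0.179, collagen list median 0.02, adjusted p = 0.857), FGF2 (0.77) and BMP4 (1.12) among growth factors (0.11, 0.0838), JUND (1.05) among immediate early genes (median -0.01, mean 0.11, 0.433) and CEBPB (0.88) and CALR (-0.70) of the unfolded protein response (median 0.08, mean -0.04, 0.785). BAX (1.01, -0.24 at its other probe) was past it among p53 targets (0.08, 0.117), BCL2L1 (0.90, 0.30 at its other probe) among apoptosis regulators (median -0.05, mean 0.04, 0.828), ACLY (0.82, -0.24 at its other probe) in fatty acid synthesis (-0.18, 0.208) and SGMS1 (0.69) among sphingolipid genes (-0.06, 0.973). S100A6 (0.75) was past it in the S100 family (-0.21, 0.771), DNAJA1 (0.93) in heat shock (median -0.07, test upward, 0.973), WASF2 (-0.62) in actin genes (median 0.01, mean -0.03, 0.885), SNAI2 (-0.78) in epithelial-mesenchymal transition (-0.24, 0.208) and DHCR7 (-0.74) in cholesterol synthesis (-0.19, 0.0501). These calls ended without control fat pad array 1 or 2 or knockdown lung array 1 or 2, at adjusted p up to 0.464 over all settings. All but THBS1, CEBPB and BAX also ended without knockdown fat pad array 1, most of these without knockdown fat pad array 2 or control lung array 2 as well, and SGMS1 and CALR also without control lung array 1. Medians of the other lists were -0.11 for matrix proteases (adjusted p = 0.0890), 0.08 for G1/S (0.165), -0.04 for oxidative phosphorylation (0.678), 0.59 for MHC class II (0.165), -0.06 for melanocyte genes (0.678), -0.15 for integrins (0.202) and -0.05 for housekeeping genes (0.386). The cholesterol list, lower under each of 6 background and normalization settings with the reported one included, was called under 4 of them, and in knockdown cells alone under 6 (median -0.27, adjusted p = 0.0032, adjusted p = 0.484 with an estimated correlation, 0.104 without knockdown fat pad array 2).

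In all, limma called 293 genes higher and 167 lower in lung metastases, 194 and 36 of them by 2-fold or more (3183 at an unadjusted p under 0.05). Without 1 array the calls numbered 24 (control fat pad 1), 40 (control fat pad 2), 199 (knockdown fat pad 1), 419 (knockdown fat pad 2), 908 (control lung 1), 325 (control lung 2), 82 (knockdown lung 1) and 36 (knockdown lung 2), and 685 without both arrays that stood apart. Scaling arrays to equal medians moved the median of the 16589 tested genes by -0.36 and called 241 genes higher and 3869 lower. Directions here are therefore relative to a quantile-normalized whole. The scaling used the median over all probes, of which 35.1% to 40.8% were detected per array, so it rested on undetected probes and not on expressed genes. Camera called 5 lists up and 4 down, of which 0 held with an estimated correlation (5 at an unadjusted p under 0.05), and fry called 8. The files give no slide or day, and sample numbers run in separate blocks for the sites, so if those mark batches, batch and site cannot be told apart.

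Within control cells 61 genes were higher in lung and 12 lower, and within knockdown cells 32 and 8. Under median scaling the counts were 162 higher and 4450 lower in control cells, and 63 and 32 in knockdown cells. In control cells EFNB2 (5.50 ± 0.438, adjusted p = 0.00425) and PTPRB (4.80) read higher and STX8 (-2.09 ± 0.200) lower. The knockdown arrays gave HBA2 (3.98 ± 0.273), SPARCL1 (4.25 ± 0.356), CXCL8 (2.69 ± 0.215, adjusted p = 0.00437) and IFIT1 (2.54 ± 0.185, adjusted p = 0.00261). HBA2 and IFIT1 held without any 1 array in knockdown cells. EFNB2 and STX8 were lost without control fat pad array 1 or 2, PTPRB without control fat pad array 2, SPARCL1 without knockdown lung array 1 or 2 and CXCL8 without knockdown lung array 2 (adjusted p up to 0.178). Left out singly, arrays moved the counts between 2 and 777 in control cells and between 5 and 112 in knockdown cells. The site differences of the lines share no arrays and correlated across genes at r = 0.397 (Spearman 0.280), where genes are not independent replicates. Of 713 genes at an unadjusted p under 0.05 in both lines 678 went the same way, where both tests use the same pooled variance of each gene.

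The interaction asks whether knockdown acted differently in lung and in the fat pad. Limma called 0 genes (1104 at an unadjusted p under 0.05, smallest adjusted p = 0.733), and 1 with an intensity trend and robust variances. More genes passed without knockdown fat pad array 1, where array 2, which stood apart, alone stood for its group. SPHK1 (-0.02, adjusted p = 0.995) and FSCN1 (0.17, adjusted p = 0.932) were not past the test, and the smallest p belonged to IFIT1 (1.92 ± 0.262), ZNF559, a zinc finger gene undetected in control lung (a ratio of folds of at least 2.77), and OAS1, an RNA sensor (1.35). Camera called 6 of 37 lists, of which 0 held with an estimated correlation and fry called 0 (0 and 2 at an unadjusted p under 0.05). Median scaling, which rested on undetected probes, moved the median of all tested genes by 0.36 in the interaction, by 0.24 for knockdown in lung and by -0.56 for site in control cells. Of 36 interferon genes 35 had a positive interaction (median 0.71, adjusted p = 1.01e-15, adjusted p = 0.854 with an estimated correlation, up to 7.72e-06 without 1 array). Their median knockdown difference was -0.96 in the fat pad (adjusted p = 1.23e-36, adjusted p = 0.23 with an estimated correlation). In lung it was -0.33, or 0.10 under median scaling (adjusted p = 7.66e-05, adjusted p = 0.578 with an estimated correlation, 0.261 without control lung array 2). Between sites the list had a median of 1.26 in knockdown cells (adjusted p = 5.46e-38, adjusted p = 0.284 with an estimated correlation). In control cells it was 0.49, or -0.28 under median scaling (adjusted p = 1.67e-09, adjusted p = 0.611 with an estimated correlation).

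**Figure D4:**
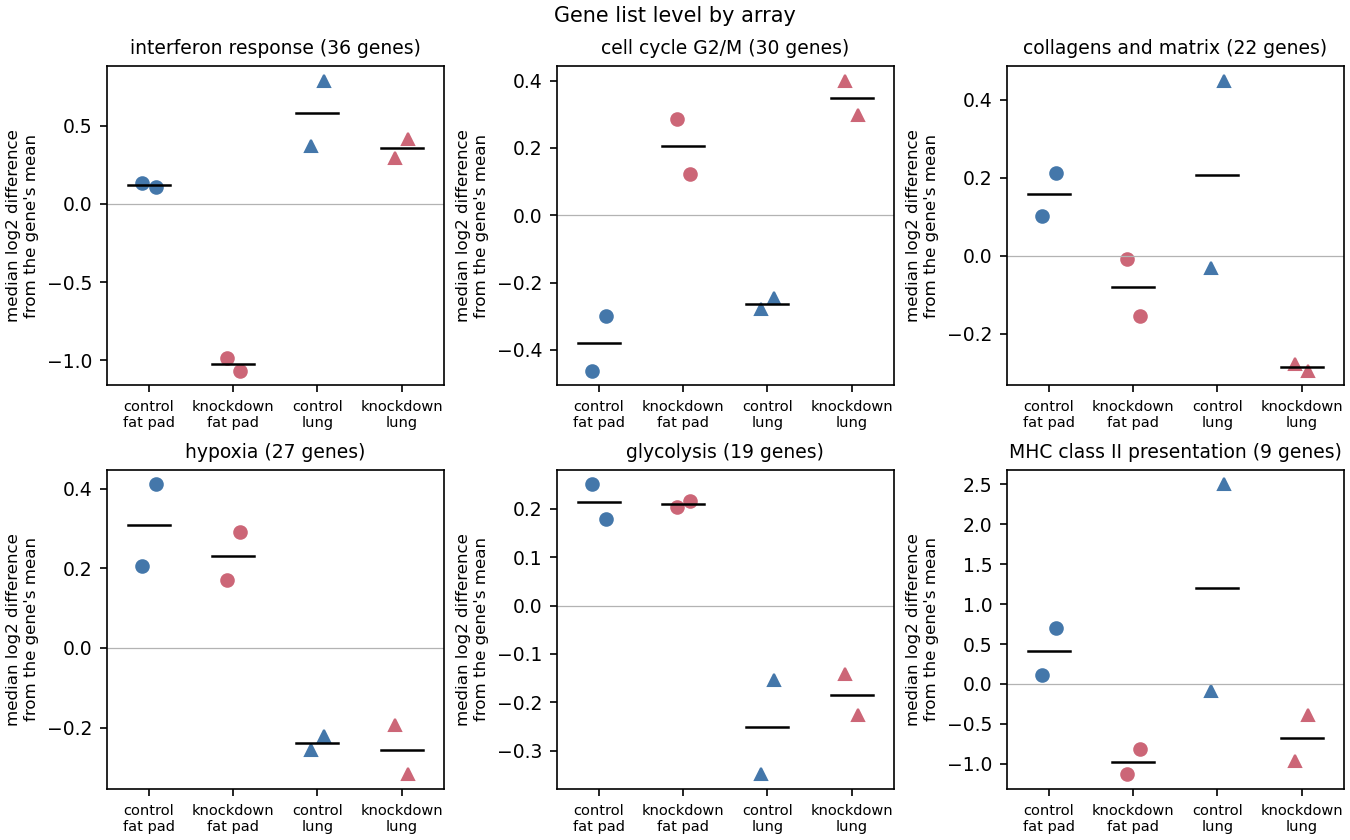
Median difference from each gene's mean (log2) of 6 gene lists on each array, with control arrays in blue, knockdown arrays in red, circles for fat pad and triangles for lung. Interferon genes sit at -0.98 and -1.07 in knockdown fat pad tumours and between 0.10 and 0.79 on the other arrays, and the list's lung against fat pad difference in control cells turns from 0.49 to -0.28 under median scaling.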

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

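The tests of mouse RNA for the lung rises, host tissue, dilution, normalization and single arrays were chosen after the results were seen, whereas the other probes of interferon genes, the unrelated line difference and the other splits were set beforehand. A test of the interaction drew attention to 6 gene lists, which is a difference of the knockdown effect between lung and fat pad. They were interferon response (median interaction 0.71, adjusted p = 1.01e-15), ribosomal proteins (0.28, adjusted p = 0.00215), oxidative phosphorylation (0.26, adjusted p = 0.00672), melanocyte lineage (0.49, adjusted p = 0.034), collagens (-0.32, but 0.14 under median scaling, adjusted p = 0.034) and fibroblast markers (-0.29, but 0.04 under median scaling, adjusted p = 0.034). With an estimated correlation each had an adjusted p of 0.854, and fry called 0 of 37 lists (2 at an unadjusted p under 0.05). Calls ended for oxidative phosphorylation without knockdown fat pad array 2 or control lung array 2 (adjusted p up to 0.519), and for melanocyte genes without knockdown fat pad array 2 or knockdown lung array 2 (up to 0.28). The collagen and fibroblast calls ended without control fat pad array 1, knockdown fat pad array 1 or control lung array 2, collagens also without knockdown lung array 2 and fibroblast markers without knockdown lung array 1 (up to 0.622). Without 1 array ribosomal proteins reached 0.0445 and interferon genes 7.72e-06. Under cyclic loess the ribosomal median was 0.048 (adjusted p = 0.85), and of 6 background and normalization settings with the reported one included 4 called ribosomal proteins, 4 collagens, 5 oxidative phosphorylation and 5 fibroblast markers.

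Lung metastases read higher for 293 genes, such as EFNB2, SPARCL1 and CYP4B1, and lower for 167. Dilution of tumour RNA stays open as a source of the falls. Melanocyte genes had a median of -0.061 (interquartile range -0.18 to 0.09) where the fallen genes had -0.79 (-0.98 to -0.69). Under median scaling they had -0.50 (-0.64 to -0.34) where the fallen genes had -1.23 (-1.40 to -1.12). In control cells under median scaling these were -0.98 (-1.33 to -0.70) and -1.50 (-1.70 to -1.29). The fallen genes were picked for low values in the same averaged comparison, and quantile normalization removes an even dilution, so this test cannot decide. Mouse lung RNA read by human probes stays open for the rises. Of their other probes 16.8% follow, against 66.7% for knockdown-changed genes (Fisher's exact p = 2.35e-10, with probes counted as independent). However, genes that fell in lung had 45.7% and genes that fell with knockdown 50%. Since dilution by host RNA stays open for the falls in lung, those genes are not a reference free of mouse RNA. Unequal amounts of host tissue stay open too, since the 32 genes that rose in knockdown lung were higher by a median of 0.39 (interquartile range 0.00447 to 0.643) on control lung array 2 than on array 1. A change in the tumour cells themselves may account for part, such as CXCL8, which mice lack. Of 34 splits of the arrays only 1, the real one, gave as many genes (490 in an additive fit, 72 at most in the others). The other splits leave the site difference in their residual, which lowers their counts. Neither chance nor a batch that follows site is excluded by this.

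Interferon genes were lower in knockdown tumours, and more so in the fat pad than in lung by the preset-correlation test alone. In lung the median knockdown difference was -0.33, but 0.10 under median scaling. The list stood at 0.29 and 0.42 on knockdown lung arrays and at 0.37 and 0.79 on control lung arrays 1 and 2. Normalization is argued against for the interaction alone, since its median stayed at 0.44 or more under every background and normalization setting. A single array is argued against for it too, with a lowest median of 0.44 without any 1 array. For mouse RNA, 80% of 15 other probes of 10 interferon genes higher in knockdown lung followed that rise (95% Clopper-Pearson interval 51.9 to 95.7, with probes counted as independent). For knockdown-changed genes the share was 66.7% (Fisher's exact p = 0.369). This covers only the lung rise in knockdown cells. The knockdown difference itself was not tested this way, and the other probe of IFIT1 and some of OAS2 do not follow it, so mouse RNA stays open. No slide is given, so a batch that parts the lines within a site was not tested. A response of the tumour cells that depends on both SPHK1 and site may be behind this, as a hypothesis, with adjusted p = 0.854 for the list with an estimated correlation.

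Knockdown and control tumours differed in 145 genes, such as MT1E, GPER1 and COL5A2, while 0 of 14 list calls held with an estimated correlation (5 lists at an unadjusted p under 0.05). Less host tissue in knockdown tumours stays open as a source of the lower fibroblast markers (median -0.50, interquartile range -0.61 to -0.47). The 30 endothelial, macrophage, lymphocyte, adipocyte and erythroid markers had a median of 0.014 (-0.17 to 0.18), but the 14 of them detected on every control array had -0.15 (-0.47 to 0.14), and 3 muscle markers outside that test had -0.23. A difference between the cell lines unrelated to SPHK1 cannot be told apart from the knockdown: a single hairpin and a single control line were used, and the correlation of 0.28 across genes between sites, where genes are not independent replicates, follows from either. Of 34 splits only 1, the real one, gave as many genes (187 in an additive fit, 3 at most in the others). The other splits leave the line difference in their residual, which lowers their counts, so chance is not excluded by this. An effect of SPHK1 itself stays open and untested.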

How the results depend on the processing

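Leaving out both arrays that stand apart was chosen after seeing the data, and the other settings before. Signal over background limits genes near the detection floor such as SPHK1. Counts follow the order knockdown averaged, site averaged, knockdown in fat pad, knockdown in lung, site in control cells, site in knockdown cells and interaction (145, 460, 10, 2, 73, 40 and 0 as reported), and for each change the cause was not tested unless stated. Normexp gave 339, 702, 28, 9, 239 and 72 for the first 6, and no background correction 336, 750, 21, 12, 208 and 63. An intensity trend with robust variances gave 487, 818, 74, 60, 315, 146 and 1. Median scaling gave 4110 for site averaged, 93 and 14 for knockdown in fat pad and lung, 4612 and 95 for site in control and knockdown cells, and 19 site lists in place of 9. Knockdown in the fat pad gave 38 with cyclic loess, 17 with the deposited log2 values, 4 without the detection filter and 6 with a replicate block. Knockdown in lung gave 5 with cyclic loess, 5 with detection on all 8 arrays, 6 with every probe and 1 with only the 2 groups. Site in control cells gave 10 without the filter, 11 with only the 2 groups and 125 with a replicate block, and site in knockdown cells 19 without the filter. The replicate block gave 88 for knockdown averaged. Asking for a log2 fold change of at least 1 as well gave 93 and 230 averaged, by its construction. Without both arrays that stand apart the counts were 27, 4, 148 and 177 for the 4 comparisons within a stratum. With an estimated correlation 0 knockdown lists and 0 site lists were called (5 and 5 at an unadjusted p under 0.05), and fry called 7 knockdown lists in place of 14. SPHK1 had a log2 fold change of -1.73 without the filter (adjusted p = 0.0733) and of -1.73 with a replicate block (adjusted p = 0.0512), -0.21 at its other probe (adjusted p = 0.612), and no value under detection on all 8 arrays.

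With each array left out in turn, where the lone array of a group is assumed to vary like the other groups, counts ran from 3 to 707 for knockdown averaged, 24 to 908 for site averaged, 1 to 47 and 1 to 556 for knockdown in fat pad and lung, 2 to 777 and 5 to 112 for site in control and knockdown cells, and 0 to 261 for the interaction. SPHK1 ran from -1.96 to -1.49, and lists from 12 to 15 for knockdown and 8 to 14 for site. Of 37 named genes called for knockdown averaged 2 kept the call without any 1 array, and of 50 for site averaged 14. Of 19016 values of named genes under all settings, most of them not past the threshold as reported, 17499 kept direction and side of it, 635 fell short of it, 620 newly passed it and 262 turned sign, 0 of these past the threshold in either fit. The highest interaction count came without knockdown fat pad array 1, where array 2, which stood apart, alone stood for its group. A slide block was not run, since the files give no slide.

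With normexp the turned values were, for knockdown averaged CD79B -0.014 and ALAS2 0.018. With no background correction the turned values were, for knockdown averaged CD79B -0.0097 and ALAS2 0.0054. With median scaling the turned values were, for knockdown averaged ENG 0.024, CD79A 0.050 and ALAS2 0.045; for site averaged FSCN1 -0.51, PLPP1 -0.26, TJP1 -0.070, PRIM1 -0.085, PCNA -0.15, CENPE -0.038, TTK -0.20, DLGAP5 -0.21, UQCRB -0.19, HSPA8 -0.14, TAP2 -0.064, CDKN1A -0.0085, BBC3 -0.092, KRT15 -0.30 and ROBO4 -0.061; for knockdown in fat pad CD79B 0.00028; for knockdown in lung BIRC2 0.087, MC1R 0.031 and ENG 0.31; for site in control cells IRF1 -0.29, TJP1 -0.21, CCNE2 -0.021, CCNE1 -0.16, CENPE -0.24, CCNB1 -0.43, KIF2C -0.30, SC5D -0.35, SERPINH1 -0.27, TAP2 -0.34, TAP1 -0.35, HLA-DRA -0.033, SDC2 -0.041, CDKN1A -0.039, PMAIP1 -0.015, KRT15 -0.41, PNPLA2 -0.15, ROBO4 -0.32 and LYZ -0.29; for site in knockdown cells FSCN1 -0.15, RPLP0 -0.13, KRT18 -0.010 and KRT15 -0.20; for the interaction SPHK1 0.68, CERK 0.021, PXN 0.035, CCNB1 0.12, CDC20 0.25, ELOVL1 0.22, PDIA4 0.13, HSPA1B 0.11, HLA-DRB3 0.17, IFI30 0.11, COL1A2 0.020, CDKN1A 0.061, MT1A 0.0045, KRT15 0.21, CLDN5 0.069 and PECAM1 0.41. With cyclic loess the turned values were, for knockdown averaged HBA2 -0.13 and ALAS2 0.047; for site averaged SPHK1 0.0084; for knockdown in fat pad CD79B 0.014; for knockdown in lung HBA2 -0.27; for site in control cells FSCN1 0.040 and LAMP3 0.088; for site in knockdown cells SPHK1 0.15; for the interaction SPHK1 0.29, CLDN5 0.046 and PECAM1 0.12. With no detection filter the turned values were, for site in knockdown cells AGER 0.15. With both arrays that stand apart left out the turned values were, for knockdown averaged AQP5 0.047, KRT8 -0.067, ENG 0.20, MYH6 0.065 and ALAS2 0.18; for site averaged SPHK1 0.40, FSCN1 -0.28, CD74 -0.42, CIDEA 0.0012, FABP4 -0.55 and CD2 0.016; for knockdown in fat pad LAMP3 -0.093, KRT18 0.014, PRLR 0.18, LEP -0.59, ENG 0.11, AIF1 -0.29, CD79A -0.13, CD79B 0.35 and MYH6 -0.047; for knockdown in lung AQP5 0.073, KRT8 -0.26, ENG 0.30, C1QA 0.072, MYH6 0.18 and ALAS2 0.33; for site in control cells SPHK1 0.41, HLA-DMB -0.40, HLA-DRB4 -0.52, HLA-DRA -0.85, FABP4 -0.82, LYZ -0.16, MYH6 -0.33 and HBG1 0.067; for site in knockdown cells SPHK1 0.40, LEP 0.067 and MYL1 -0.090; for the interaction HSPE1 -0.099, IFI30 0.35, HLA-DMA 0.061, HLA-DMB 0.59, MT1X 0.11, MT1A 0.076, AQP5 0.053, KRT15 0.011, CLDN5 0.23, CD34 0.014, PECAM1 0.46, LAPTM5 0.074, AIF1 1.14, CD79B -0.33, MYH6 0.22 and ALAS2 0.29. Without 1 array they ran, for knockdown averaged AIF1 -0.012 to 1.37, ALAS2 -0.40 to 0.25, AQP5 -0.78 to 0.032, CD2 -0.012 to 0.18, CD79A -0.21 to 0.18, CD79B -0.18 to 0.19, ENG -0.31 to 0.087, HBG2 -0.50 to 0.11, KRT8 -0.061 to 0.21, LEP -1.27 to 0.039, MYH6 -0.38 to 0.17 and PDPN -0.030 to 0.30; for site averaged CD2 -0.15 to 0.038, CD68 -0.00042 to 1.38, CD79B -0.33 to 0.039, FABP4 -0.44 to 1.64, FSCN1 -0.25 to 0.27, HLA-DRB4 -0.022 to 1.88, MYH6 -0.32 to 0.23, PRLR -0.11 to 0.25 and SPHK1 -0.29 to 0.18; for knockdown in fat pad AGER -0.34 to 0.15, AIF1 -0.29 to 2.46, CD2 -0.21 to 0.17, CD34 -0.093 to 0.54, CD79A -0.13 to 0.67, CD79B -0.40 to 0.35, ENG -0.36 to 0.11, HBD -0.048 to 0.27, IL7R -0.21 to 0.42, KRT18 -0.35 to 0.014, LAMP3 -0.093 to 0.37, LEP -0.59 to 2.04, MYH6 -0.047 to 0.38, MYL2 -0.072 to 0.019, PDPN -0.25 to 0.41 and PRLR -0.21 to 0.18; for knockdown in lung ABCA3 -0.017 to 0.87, ALAS2 -0.97 to 0.33, AQP5 -1.56 to 0.073, C1QA -0.89 to 0.072, CD34 -0.19 to 0.48, CD79B -0.067 to 0.13, ENG -0.50 to 0.30, HBA2 -0.063 to 0.60, KRT8 -0.26 to 0.29, LAPTM5 -0.024 to 0.49 and MYH6 -0.92 to 0.18; for site in control cells ENG -0.74 to 0.058, FABP4 -0.82 to 3.33, FSCN1 -0.60 to 0.44, HBG1 -0.59 to 0.18, HLA-DMB -0.40 to 2.54, HLA-DRA -0.85 to 2.38, HLA-DRB4 -0.52 to 3.28, LAMP3 -0.24 to 0.043, LYZ -0.16 to 0.67, MYH6 -0.33 to 0.77, PRLR -0.013 to 0.72, ROBO4 -0.16 to 0.22 and SPHK1 -0.51 to 0.41; for site in knockdown cells ABCA3 -0.26 to 0.62, AIF1 -0.28 to 2.48, CD2 -0.15 to 0.24, CD79A -0.17 to 0.63, CD79B -0.49 to 0.25, FSCN1 -0.077 to 0.27, KRT15 -0.046 to 0.16, LEP -2.56 to 0.067, MYL1 -0.090 to 0.30, PNPLA2 -0.71 to 0.14 and SPHK1 -0.54 to 0.40; for the interaction AIF1 -2.20 to 0.56, ALAS2 -1.14 to 0.16, AQP5 -1.55 to 0.083, CD34 -0.42 to 0.26, CD79B -0.32 to 0.43, CLDN5 -0.50 to 0.32, FSCN1 -0.34 to 0.69, HLA-DMA -1.88 to 0.37, HLA-DMB -2.42 to 0.52, HLA-DRB3 -0.89 to 0.071, HSPA1B -0.89 to 0.11, IFI30 -0.91 to 0.041, KRT8 -0.39 to 0.16, LAPTM5 -0.81 to 0.0017, LYZ -0.22 to 0.61, MYH6 -1.08 to 0.012, PECAM1 -0.46 to 0.35 and SPHK1 -0.49 to 0.45.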

Other observations

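The run of genes on chromosome 20 was tested only after its values were seen, and the rule that reads neighbouring genes beside the site comparison was added after as well. A candidate explanation of part of the knockdown difference is a copy number change carried by 1 of the lines, which would move neighbouring genes together at both sites. Medians of 257 windows of 50 neighbouring genes, placed for 13407 genes in their GRCh38 order, correlated between fat pad and lung at r = 0.43 for knockdown against control, where genes are not independent replicates (95th percentile of 1000 random orders 0.276, with 0 as high). The site comparison, which no line difference would give, correlated between lines at 0.482 (random 95th percentile 0.332), so neighbouring genes move together for other reasons too and copy number cannot be told apart from them. The largest run for knockdown covered 150 genes on chromosome 20 from DEFB127 to TRPC4AP, with a mean of window medians of 0.24 (random 95th percentile 0.175, 0 of 1000 as large, permutation p = 0.001, the smallest that 1000 orders can give). In it 113 of 150 genes were higher, 2 were called, and medians were 0.24 in the fat pad, 0.21 in lung and 0.06 between sites. The other full windows of chromosome 20 were also higher at both sites, with averaged medians of 0.064, 0.090 and 0.144. Window medians on other chromosomes ran from -0.139 on chromosome 1 to 0.253 on chromosome 22. The largest run for site, on chromosome 19, also exceeded chance (-0.17, random 95th percentile 0.149, 8 of 1000 as large), so the chromosome 20 run stays undecided.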
